A study of Balaenoptera physalus with 6 samples.

How the data were processed

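Genomic DNA from 6 fin whale skin samples, 3 labelled high and 3 labelled low in organochlorine (OC) concentration, was digested with MspI, bisulfite-treated and sequenced on an Illumina HiSeq, per the labels' protocols. Bismark was used by the authors, per the submitters' processing notes; its version, the genome build, the annotation and the read filters are not given in the sources used here. For each cytosine the authors deposited a methylation level per sample as a fraction, rounded to 2 decimals, and the coverage per sample as a count of reads, per the file headers. The deposited tables also gave the difference of group means as a fraction, a p-value and a class for each site, and, for listed sites, the names of genes whose promoter, exon or intron holds the site. How far a promoter reaches is not given in the sources used here. Recomputed from the levels, an equal-variance two-sample test returned the p-value of the authors' deposited table at 99.8% of listed CpG sites, so those values are not adjusted for the number of sites.

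Lists of different sites were analysed in full: 32682 CpG, 1742 CHG and 3216 CHH sites. The shorter deposited lists held the same sites with the same differences. The tables of all tested sites were analysed only for their first part, which lies on scaffold NW_006724458_1 between starts 51548 and 1103801 for CpG; the rest was not analysed here. Results on unselected sites hold for that stretch only, and the listed sites have no background of tested sites. Methylated reads were taken as the level times the coverage, rounded; the levels matched those counts at all listed CpG sites within rounding. Coverage had a minimum of 5 reads, and 12062 of the listed CpG sites had at least 10 reads in each sample. At 11.4% of listed CpG sites all 6 coverages were even, where 1.56% would be by chance, and methylated counts were even at 93.3% of those values against 51.9% elsewhere. Reads counted doubly would make intervals too narrow. RRBS reads carried no molecular identifiers in the sources used here, so intervals and floors cover counting error only.

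Unselected sites with at least 10 reads in each sample were tested with a two-group logistic model per site on methylated and unmethylated reads, with a Pearson overdispersion floored at 1 and squeezed across sites with limma 3.58.1 in R 4.3.3, an F test and Benjamini-Hochberg adjustment at 0.05. Data were simulated for 292 CpG sites of this depth with 40 changed sites. Their overdispersion was set at 0.02 and not estimated from these samples, so the shares hold for that setting only. The model recovered 71.8% of changes of 30 points and 100% of changes of 60 points, and 9.01% of its calls were false, above the 5% aimed at. For 335 CHG sites the false share was 8.79% and for 304 CHH sites 5.93%. Mean levels per sample were compared by an exact two-sided permutation test. Listed sites were described, not retested: group levels are means ± SD of the 3 samples, and "higher" and "lower" refer to high against low OC. Sites and genes to name were fixed before the data were examined: sites with all samples of a group above all of the other, ranked by absolute difference, 1 per gene, 12 per direction for CpG and 3 per direction for CHG and CHH, up to 2 positions with no gene, and up to 20 genes of the fixed lists. The rule was applied to calls on the unselected sites. It foresaw the authors' listed sites only where no test was possible or no site passed. Since the lists allow no test, it was applied to the authors' listed sites as well. A site on the unselected stretch had passed, so this departs from the rule as written. The 17 fixed gene lists held markers of skin cell types and pathways, and 82.0% of the gene names at listed CpG sites matched a symbol in the RefSeq gene table of fin whale assembly mBalPhy2.hap1.1, used for names only.

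After the data were seen, Fisher's exact test of higher against lower listed sites per location (calls at a Benjamini-Hochberg adjusted p under 0.05 over the 12 comparisons of a setting), Fisher's exact test of the direction of each gene list, runs of neighbouring sites, promoters with at least 6 listed sites and a model with reads halved at sites with only even counts, which called 3 CpG, 0 CHG and 1 CHH sites, were added. Alternatives set before the data were examined were coverage minimums of 5 and 20 reads, a cap at the 99.9th percentile of coverage, no squeezing, Fisher's exact test on summed reads, limma on log2 ratios with 1 read added, a minimum difference of 20 points, extreme sites left out, and each sample left out in turn; for levels, a coverage-weighted mean and a median; and for the lists, a difference of at least 50 points, at least 20 reads, 1 site per 1 kb window and sites with levels near 0, 50 or 100% in all samples left out. Samples left out of a list were left out among sites that the authors had chosen with all 6. Statistics used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.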

Results

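Reduced representation bisulfite sequencing (RRBS) was used to read cytosine methylation in skin of the fin whale, Balaenoptera physalus, from the Mediterranean. In RRBS the restriction enzyme MspI cuts at CCGG, which concentrates the reads on CpG-rich sequence, and bisulfite then converts unmethylated cytosine, so that the share of reads that still show a cytosine is the methylation level of that site. The labels placed 3 skin samples in a group with a high concentration of organochlorine contaminants (high OC) and 3 in a group with a low concentration (low OC), and the study asked whether methylation differed with contaminant load. Sites were given in the CpG context and in the CHG and CHH contexts, in which H is any base but G. Sample titles began with BPT in all high OC samples and with BPL in all low OC samples. What these prefixes mark is not given in the sources used here, so it cannot be told apart from contaminant load. Each sample had its own title, but nothing in the labels says that the samples came from separate animals. The p-values of the permutation test therefore measure the spread between these samples. Those of the model do so only in part, since the overdispersion of each site was squeezed towards that of the other sites. Those counted over reads, sites, runs or genes do not include this spread. Unselected sites were analysed on the first part of 1 scaffold only, NW_006724458_1, with 651 CpG, 658 CHG and 662 CHH sites, and the sites that the authors listed as different were analysed over the whole assembly. Median coverage of the unselected CpG sites was between 13 and 16 reads per sample, and that of the listed CpG sites between 12 and 14 reads. At such depth the level of a single site in a single sample moves in steps of several percentage points. The name of the assembly is not given in the sources used here, and positions are printed as the deposited tables give them. Its scaffold names were not those of the fin whale assembly used for gene names. Whether the reads were aligned to a fin whale genome is therefore not known here.

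With every site weighted equally, average methylation of the unselected sites did not separate the groups in any context. In CpG context, the 292 sites with at least 10 reads in each sample averaged 29.6% ± 0.584 (SD, n = 3) in high OC and 27.8% ± 2.38 (SD, n = 3) in low OC skin. The 3 low OC samples stood at 25.5%, 27.4% and 30.3%, a spread that included all 3 high OC samples (29.2%, 30.2% and 29.2%). Outside CpG, methylation was close to the floor: 335 CHG sites averaged 1.06% ± 0.0821 (SD, n = 3) against 0.886% ± 0.205 (SD, n = 3), and 304 CHH sites averaged 0.899% ± 0.274 (SD, n = 3) against 0.792% ± 0.176 (SD, n = 3). The exact two-sided permutation test gave p = 0.4 for CpG, p = 0.2 for CHG and p = 0.6 for CHH, and 3 samples against 3 cannot go below p = 0.1. With sites weighted by coverage, CHG (1.67% ± 0.134 (SD, n = 3) against 1.49% ± 0.0549 (SD, n = 3)) and CHH (0.868% ± 0.0896 (SD, n = 3) against 0.714% ± 0.0608 (SD, n = 3)) reached that limit (exact permutation p = 0.1), while CpG did not (p = 0.9). Only 3 of the 658 CHG sites had a mean level over 50%, and 0 of the 662 CHH sites did, which allows a share of up to 0.453%.

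On the same stretch, 3 CpG sites, 0 CHG sites and 1 CHH site passed a logistic model with overdispersion at a Benjamini-Hochberg adjusted p of 0.05. The CpG site at 697272 on the minus strand was lower in high OC skin, at 66.3% ± 4.33 (SD, n = 3) against 95.4% ± 3.99 (SD, n = 3). Its adjusted p was 0.0229, its coverage ran from 24 to 49 reads, and the authors' deposited table also called it hypomethylated. The other passing sites did not have all samples of a group above all of the other, and they are named here after their values were seen. The CpG site at 595937 on the plus strand, covered by 1081 to 1493 reads, was lower in high OC skin by a small amount, at 59.0% ± 4.01 (SD, n = 3) against 65.0% ± 3.62 (SD, n = 3), with an adjusted p of 0.0129. The CpG site at 818284 on the plus strand averaged 74.6% ± 16.3 (SD, n = 3) against 42.4% ± 37.2 (SD, n = 3), with an adjusted p of 0.0419. The passing CHH site, at 595940, had 1.03% in high OC replicate 2 and 0% in each of the other samples, at 1080 to 1494 reads and an adjusted p of 0.0432. Deposited levels are rounded to 0.01, so a level given as 0% there can stand for up to 0.5%, and this call can rest on the rounding. No gene is given for the site at 697272 in the list of different sites. At an unadjusted p under 0.05 the model counted 22 CpG, 20 CHG and 12 CHH sites. For CHG, Fisher's exact test on summed reads also called 0 sites, with 10 at an unadjusted p under 0.05, and limma called 0, with 12. The CpG calls were not stable: limma called 0 and Fisher's exact test on summed reads 7. The model called 0 without high OC replicate 2 and 0 without low OC replicate 2, and it called 10 without low OC replicate 3. With the overdispersion of each site left unsqueezed, the model called 0 CpG sites (lowest adjusted p = 0.743) and 0 CHH sites (lowest adjusted p = 0.761). The calls thus rest on the overdispersion shared across sites.

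The authors' deposited tables listed 32682 CpG sites on 459 scaffolds as different between the groups, and the sites that were higher in high OC skin lay in promoters more often than those that were lower. On the unselected stretch the authors called 2.0% of the 651 CpG sites. By their criteria recomputed there, 6 of the 10 divisions of the samples into 3 and 3, the real groups included, gave at least as many sites. The number of listed sites is thus by itself no evidence that the groups differ. Of the 16600 higher sites, 10.7% lay in a promoter, against 5.78% of the 16082 lower sites. Exons held 19.5% of the higher and 15.5% of the lower sites, introns held 37.3% and 37.8%, and 40.9% and 45.7% had no gene. At the promoter sites listed as higher, mean methylation was 44.9% in high OC and 25.1% in low OC skin, over 1172 genes. At those listed as lower it was 28.1% and 46.3%, over 778 genes. Of 1820 genes with a listed promoter site, 1042 had only higher sites, 648 only lower sites and 130 both. The difference in promoter share was 4.97 percentage points (Fisher's exact test, two-sided, adjusted p = 1.79e-59 over 12 comparisons), and that in exon share 3.96 points (adjusted p = 2.81e-20). The test treats sites as independent, which neighbouring sites are not. With 1 site per 1 kb window the promoter difference was 4.0 points (Fisher's exact p = 4.73e-30). Among the 718 sites that differed by at least 50 points the promoter call was lost (4.08 points, Fisher's exact p = 0.0186, adjusted p = 0.224) and the exon difference turned to -3.76 points (Fisher's exact p = 0.0996).

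**Figure D1:**
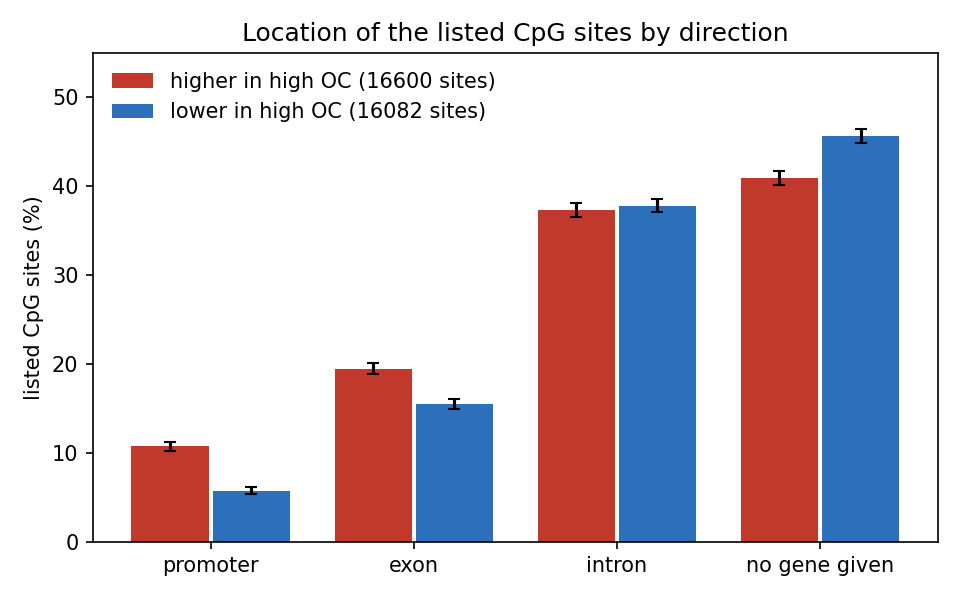
Share of the listed CpG sites (percent, vertical axis) that lay in a promoter, an exon, an intron or no named gene, for the 16600 sites higher in high OC skin (red) and the 16082 sites lower (blue); error bars are exact 95% binomial intervals, and a site can fall in more than 1 class. Promoters held 10.7% of the higher and 5.78% of the lower sites.

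Counted alone, the listed CpG sites were split almost evenly, with 50.8% higher in high OC skin (exact 95% interval 50.2% to 51.3%, exact binomial p = 0.00424). With 1 site per 1 kb window the share turned to 48.9% (exact binomial p = 0.00119), and it was 49.4%, 49.6% and 49.7% without high OC replicates 1, 2 and 3. It rose to 54.6% with at least 20 reads in each sample (exact binomial p = 6.76e-06), 52.8% without low OC replicate 2 (exact binomial p = 1.26e-13) and 51.1% without low OC replicate 3 (exact binomial p = 0.00234). Sites listed as strongly different, by at least 0.33 on the authors' scale, numbered 2204 higher and 2164 lower. In 99.6% of the listed CpG sites all samples of a group lay above all of the other, as a selection by a two-sample test on the same samples all but requires. The lists were chosen by the authors on these same 6 samples, by an absolute difference of at least 0.1 and an unadjusted p of at most 0.05 in the deposited table, so they are no independent evidence of direction.

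In promoters with many listed CpG sites, the listed sites were mostly higher in high OC skin, those of OTX1 first among them. The levels below are means over listed sites only, which the authors had selected to differ between the groups. Other CpG sites of these promoters were not analysed, so the level of a whole promoter was not measured. The gaps between groups and the small SDs follow in part from that selection. OTX1, a homeobox gene of forebrain and sense organ development, had 18 listed promoter sites, all higher, and averaged 88.8% ± 2.12 (SD, n = 3) in high OC against 42.3% ± 21 (SD, n = 3) in low OC skin. HOXC10, a homeobox gene of posterior body patterning, had 9 promoter sites at 51.4% ± 3.08 (SD, n = 3) against 18.9% ± 12.5 (SD, n = 3). HAND1, a transcription factor of heart and trophoblast development, had 8 at 39.1% ± 2.27 (SD, n = 3) against 12% ± 1.48 (SD, n = 3). SOX14 had 8 at 70.5% ± 7.98 (SD, n = 3) against 43.6% ± 3.71 (SD, n = 3), SOX7 had 6 at 52.0% ± 5.11 (SD, n = 3) against 19% ± 5.66 (SD, n = 3), and EMX1, a homeobox gene of the cerebral cortex, had 7 at 32.4% ± 0.99 (SD, n = 3) against 16% ± 1.19 (SD, n = 3). NFE2L3, a relative of the stress regulator NRF2, had 13 at 43.6% ± 2.85 (SD, n = 3) against 15.8% ± 2.96 (SD, n = 3). ALDH1A3, which makes retinoic acid, had 10 at 36.4% ± 1.15 (SD, n = 3) against 16.7% ± 3.80 (SD, n = 3), and FZD10, a WNT receptor, had 6 at 52.6% ± 3.55 (SD, n = 3) against 25.9% ± 2.91 (SD, n = 3). Of the 36 promoters with at least 6 listed sites, transfer RNA genes left aside, 27 had only higher sites, 8 had both kinds and 1 had only lower sites. That promoter belonged to LRRC55, an auxiliary subunit of BK potassium channels, with 14 sites at 54.9% ± 6.35 (SD, n = 3) against 86.3% ± 5.72 (SD, n = 3). These promoters were singled out after their values were seen, and not by rank alone. Others had as many sites or as large differences. LOC103010225 had 17 higher sites at 59.8% ± 2.61 (SD, n = 3) against 32.5% ± 3.45 (SD, n = 3). HENMT1 had 7 at 67.0% ± 16.7 (SD, n = 3) against 23.2% ± 10.3 (SD, n = 3). By promoter sites alone, 7 developmental transcription factors of the fixed list leaned higher and 3 lower. That share of 70% did not depart from the 61.6% of other genes (Fisher's exact p = 0.750). The transfer RNA names TRNAG-CCC (8 higher and 13 lower sites) and TRNAE-UUC (7 higher and 13 lower) each stand for many gene copies and are uncertain.

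**Figure D2:**
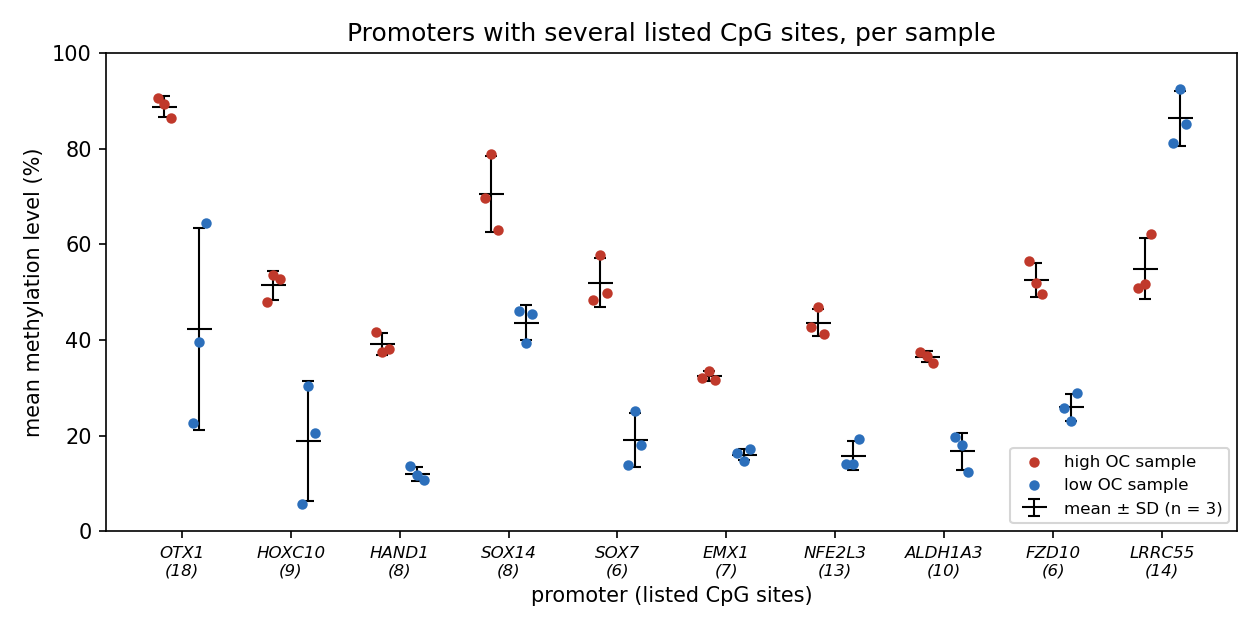
Mean methylation level (percent, vertical axis) over the listed CpG sites of 10 promoters, the number of sites in brackets, in each of the 3 high OC samples (red) and 3 low OC samples (blue), with mean and SD in black. LRRC55 is lower in high OC skin, at 54.9% against 86.3%, and the other promoters shown are higher. The 10 promoters were picked after their values were seen.

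The listed OTX1 promoter sites spanned starts 4634173 to 4635192 on scaffold NW_006730123_1, with 6 to 45 reads per site and sample. The high OC samples averaged 90.6%, 89.4% and 86.5% there. The low OC samples were far apart, at 22.7% in replicate 1, 39.6% in replicate 2 and 64.5% in replicate 3.

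**Figure D3:**
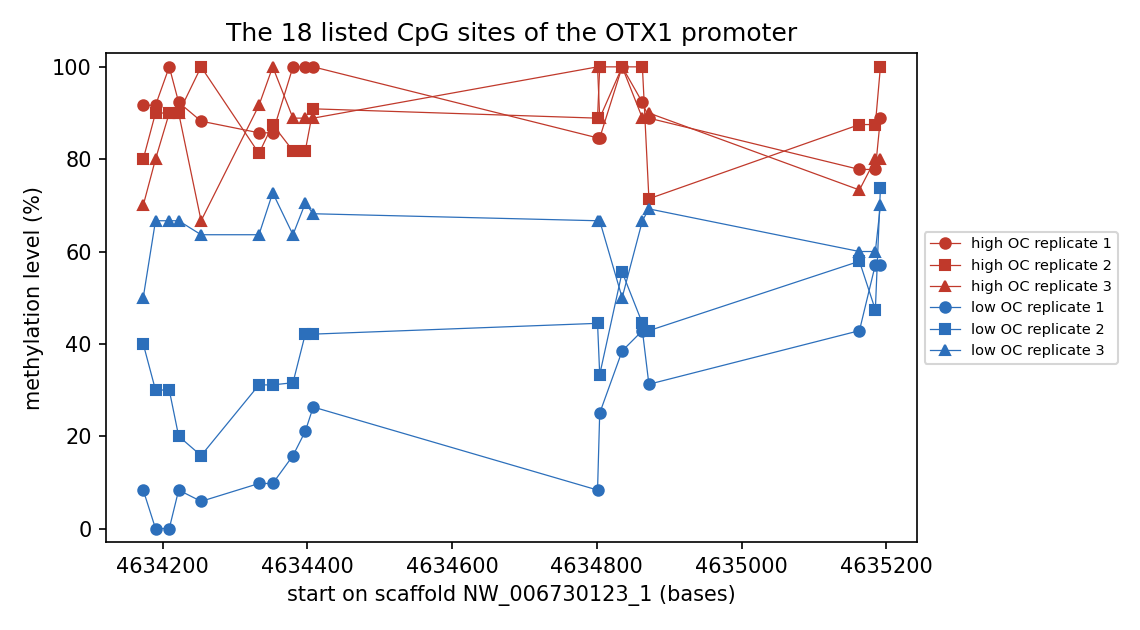
Methylation level (percent, vertical axis) of the 18 listed CpG sites of the OTX1 promoter by start position in bases on the scaffold (horizontal axis), with a line for each of the 3 high OC (red) and 3 low OC (blue) samples. The high OC samples averaged 86.5% to 90.6% and low OC replicate 3, at 64.5%, lay nearest to them.

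Neighbouring listed CpG sites mostly had the same direction, and long runs of listed sites were mostly higher in high OC skin. Levels of runs are means over listed sites only, as for the promoters. The longest run covered 40 sites within NEURL1, a ubiquitin ligase gene, from 2341489 to 2342127 on scaffold NW_006728682_1, at 35.5% ± 1.42 (SD, n = 3) against 9.74% ± 3.31 (SD, n = 3). On the scaffold that carries HOXC10, NW_006726687_1, runs of 23 sites (8290890 to 8291124) and 21 sites (8291493 to 8291968) had no gene name and averaged 61.6% ± 22.2 (SD, n = 3) against 8.98% ± 3.63 (SD, n = 3) and 54.3% ± 23.1 (SD, n = 3) against 3.71% ± 3.55 (SD, n = 3). Further along, runs of 8 sites (8326591 to 8326677) and 7 sites (8408547 to 8408709) with no gene name were lower. They averaged 12.6% ± 10.2 (SD, n = 3) against 52.2% ± 10.8 (SD, n = 3) and 33.2% ± 9.78 (SD, n = 3) against 77.8% ± 1.02 (SD, n = 3). A run of 14 sites in HOXC10 itself, at 8316592 to 8316738, averaged 60.2% ± 7.77 (SD, n = 3) against 19.99% ± 14.4 (SD, n = 3). A run of 12 sites in PTPRN2, a phosphatase-like gene of secretory granules, averaged 73.6% ± 4.08 (SD, n = 3) against 13.4% ± 2.38 (SD, n = 3). The longest run in the other direction covered 23 sites in TLX1, a homeobox gene of spleen development, at 14.1% ± 7.31 (SD, n = 3) against 45.9% ± 5.26 (SD, n = 3). PKP3, a desmosome plakophilin of the epidermis, had a run of 14 sites at 25.7% ± 3.33 (SD, n = 3) against 61.1% ± 7.18 (SD, n = 3), and FAM170B had a run of 13 at 12% ± 4.73 (SD, n = 3) against 38.4% ± 3.16 (SD, n = 3). Runs of at least 5 sites of the same direction with gaps of at most 100 bases numbered 205 higher and 73 lower (exact binomial test, two-sided, p = 1.12e-15), a definition chosen after the sites were seen. With at least 20 reads in each sample, 9 higher and 6 lower runs were left (exact binomial p = 0.607). With a sample left out, 82 to 93 runs were found, against 278 with all samples, and 71.7% to 76.9% of them were higher. A promoter was touched by 33 higher and 4 lower runs (Fisher's exact p = 0.0259), a call that was lost without any 1 of the 6 samples. Of 7440 neighbouring pairs up to 100 bases apart, 89.5% had the same direction, and this fell to 67.1% between 100 and 1000 bases and 55.2% between 1000 and 10000 bases. The closest pairs can share reads and include the 2 strands of the same CpG, so part of their agreement is built in. Runs can rest on shared reads as well. Where both strands of a CpG were listed, 680 of 746 pairs had the same direction (91.2%).

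Of 17 gene lists fixed before the data were examined, none departed from the other listed genes in direction. Among 30 developmental transcription factors with a listed CpG site, 20 had more higher than lower sites, 9 more lower and 1 equal numbers: HOXC10 had 21 higher and 0 lower, HOXD3 9 and 0, MEIS1 8 and 0, and FOXA2 6 and 0, while TBX1 had 0 higher and 6 lower. All 5 imprinted genes with unequal counts leaned higher, among them GNAS with 14 higher and 9 lower and CDKN1C with 2 and 0. Lipid and energy genes leaned higher in 13 and lower in 6 of 22, with LRP1, a lipoprotein receptor, at 10 and 1 and IRS1, an insulin receptor substrate, at 2 and 9. Xenobiotic metabolism genes were few: of 33 members 5 were listed, with AHRR, the repressor of the dioxin receptor, at 8 higher and 2 lower and ARNT2 at 4 and 3. Steroid, thyroid and retinoid genes leaned higher in 6 and lower in 9 of 16, with PGR at 4 and 0 and ESRRB at 1 and 6. DNA repair and tumour suppression genes leaned higher in 4 and lower in 9 of 15, with MGMT at 5 and 6 and FHIT at 0 and 3. Neuronal and axon guidance genes leaned higher in 12 and lower in 16 of 28, with CACNA1C, a calcium channel gene, at 31 and 85 and DSCAM at 1 and 21. WNT, Notch, Hedgehog and BMP genes leaned higher in 11 and lower in 13 of 24, DNA methylation and chromatin genes in 7 and 5 of 16, immune signalling genes in 6 and 5 of 13, and oxidative stress genes in 3 and 4 of 7. Among markers of cell types in skin, keratinocyte genes leaned higher in 6 and lower in 10 of 16, with PKP3 at 1 and 22 and EVPL at 10 and 1. Fibroblast genes leaned higher in 2 and lower in 5 of 9, endothelial genes in 2 and 7 of 9, melanocyte genes in 1 and 1 of 3, adipocyte genes in 2 and 1 of 3, and blood and immune cell genes in 2 and 1 of 3. The lowest adjusted p over the 17 lists was 0.546 (Fisher's exact test of leaning higher or lower against other listed genes, of which about 55% leaned higher). Since the full set of tested sites was not analysed here, whether a list held more listed genes than chance gives was not tested.

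Among the authors' listed sites, ranked as the fixed rule sets out with 12 per direction, the largest differences at single CpG sites of named genes lay mostly in introns. A site in an intron of PTPRN2 (6111781 on NW_006725237_1) was at 100% in all high OC samples and 6.36% ± 5.53 (SD, n = 3) in low OC skin, at as few as 5 reads. Sites in introns of GLB1L3 (382213 on NW_006728086_1), PCBP3 (728028 on NW_006725821_1) and KAZN (15252112 on NW_006726131_1) were higher by 93.3, 84.4 and 83.3 points. CLSTN1, LOC103004557, MCM2, OSBPL10, MCTP2 and SSNA1 had intron sites that were higher by 75 to 81.5 points. In the other direction, PAXIP1, a gene of the DNA damage response, had an intron site (3670729 on NW_006725237_1) at 5.56% ± 9.62 (SD, n = 3) against 100% in all low OC samples. SETD1A, a histone H3 lysine methyltransferase, had an exon site (4994399 on NW_006728570_1) at 7.41% ± 12.8 (SD, n = 3) against 92.2% ± 8.39 (SD, n = 3). Intron sites of UXS1, PDZD2, CACNA1C, CCDC93, TBC1D22A, SLC9A3 and SF3A2 and exon sites of SH3RF3 and KPTN were lower in high OC skin, with differences from -81.5 to -74.5 points. PAXIP1 also had a site that was higher (3662484, 80.8% ± 12.4 (SD, n = 3) against 0%). HSPG2, the gene of the basement membrane protein perlecan, had exon sites 2 bases apart with opposite directions: 20705990 at 81.7% ± 13.1 (SD, n = 3) against 0% and 20705992 at 15.3% ± 16.8 (SD, n = 3) against 93.3% ± 11.5 (SD, n = 3). Positions with no gene reached differences as large, with 95.2 points higher at 1425212 on NW_006734456_1 and 0% against 97.3% ± 4.62 (SD, n = 3) at 21360525 on NW_006725687_1.

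Among genes of the fixed lists, the largest site differences were mostly lower in high OC skin. TGM1, the transglutaminase of the epidermal barrier, had an exon site (12340893 on NW_006726798_1) at 27.1% ± 23.9 (SD, n = 3) against 88.9% ± 19.2 (SD, n = 3), and PKP3 an exon site (25249793 on NW_006725687_1) at 11.9% ± 3.63 (SD, n = 3) against 65.9% ± 7.23 (SD, n = 3). Sites of KCNQ1, FHIT, DSCAM, EPHB2, SEMA3A, PLXNA1, TP73 and SLIT2 were lower as well, from -60.7 points at KCNQ1 to -48.4 points at SLIT2. Higher sites lay in SHANK2 (65.4 points), NTN1 (54.2), LAMB3 (48.0), HOXC10 (47.7) and NFATC1 (47.3). LRP5 had a CHG site that was higher by 49.9 points, and AHRR had a CHH site (12819722 on NW_006731234_1) at 84.7% ± 19.7 (SD, n = 3) against 37.8% ± 3.85 (SD, n = 3), at as few as 5 reads.

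Outside CpG, the authors' deposited tables listed 1742 CHG sites (850 higher and 892 lower in high OC skin) and 3216 CHH sites (1614 and 1602). Among sites of named genes, the largest CHG differences were higher at LOC102999874 (68.7 points), DZIP1 (67.8) and KCNK17 (59.3) and lower at RANBP9 (-68.9), CACNA2D4 (-62.3) and BZRAP1 (-57.2). Among sites of named genes, the largest CHH differences were higher at ST7L (74.0 points), MLC1 (65.7) and UBE2H (62.4) and lower at SFSWAP (-65.5), LOC103015046 (-64.4) and TSPAN9 (-63.9). Positions with no gene reached 76.7 points in CHG (10643273 on NW_006725532_1) and 70.5 points in CHH context (16904282 on NW_006724459_1). Over all listed sites neither context passed a test of direction, with 48.8% of CHG sites higher (exact binomial p = 0.326) and 50.2% of CHH sites (exact binomial p = 0.846). The CHH share passed without high OC replicate 1 (53.1%, exact binomial p = 0.00362) and without high OC replicate 3 (53.3%, exact binomial p = 0.00193). Promoters held 8.35% of the higher and 5.16% of the lower CHG sites (Fisher's exact test, adjusted p = 0.0285 over 12 comparisons). That call was lost with 1 site per 1 kb window, at 50 points or 20 reads, and without high OC replicate 2 or any 1 of the low OC samples. For CHH the promoter difference was 0.51 points (Fisher's exact p = 0.573). Of pairs of neighbouring CHH sites up to 50 bases apart on a strand, 352 of 670 (52.5%) had identical methylated and total read counts in all 6 samples, against 51 of 126 CHG pairs (40.5%) and 78 of 4520 CpG pairs (1.73%).

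Genes with a listed site outside CpG were mostly genes that also had a listed CpG site. Listed CpG sites named 6197 genes, CHG sites 791 and CHH sites 1177. Of the CHG genes 591 (74.7%) also had a listed CpG site, and of the CHH genes 892 (75.8%). Of the genes with unequal counts in both contexts, 285 of 492 CHG genes (57.9%) and 418 of 747 CHH genes (56.0%) leaned the same way as in CpG. By position the overlap was smaller, since 32.7% of CHG and 34.0% of CHH sites had a listed CpG site within 1 kb. The full set of tested sites was not analysed here, so the overlap was not tested against chance.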

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

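Alternatives for the location of sites and for runs, and the fixed-list settings, were chosen after seeing the data. The higher promoter share of CpG sites kept its direction in every alternative run and its call in all but the 50-point setting (4.08 points), and 0 of 17 gene lists passed in any. The named sites, promoters and runs were selected for groups that lie apart, so leaving out a sample does not test their direction. The mean CpG level difference turned to -0.127 points as a median and was 0.389 coverage-weighted, 0.708 without low OC replicate 1 and 3.07 without low OC replicate 3; CHG and CHH medians differed by 0, the CHG difference otherwise ranged from 0.0644 without low OC replicate 1 to 0.434 at 20 reads, and the CHH difference from -0.0426 without high OC replicate 3 to 0.227 without high OC replicate 2 and 0.326 at 20 reads. Called CpG sites were 0 without squeezing, 7 with Fisher's exact test, 0 with limma and 0 to 10 with a sample left out; the CHH site was lost (0 calls) at a minimum of 5 reads, without squeezing, with Fisher's exact test, with limma, at 20 points and with extreme sites left out, and calls were 0 to 1 with a sample left out. The share of CpG sites higher in high OC was 48.9% with 1 per 1 kb, 51.8% at 50 points, 54.6% at 20 reads and 49.4% to 52.8% with a sample left out. For CHG it was 50.9% at 20 reads and 47.6% to 52.3% with a sample left out; for CHH 48.7% with 1 per 1 kb, 42.2% at 50 points, 45% at 20 reads and 48.9% to 53.3% with a sample left out. Listed sites shrank to 718 CpG, 19 CHG and 45 CHH at 50 points and 2414, 57 and 80 at 20 reads, by construction, and with a sample left out to between 17858 and 18679 CpG and 1100 and 1149 CHG sites. At 50 points the differences between higher and lower sites were -3.76 points for CpG exons, 2.68 for CpG sites with no gene, -10 for CHG promoters and -3.85 for CHH promoters. CpG introns gave 0.871 with 1 per 1 kb, 1.53 at 20 reads and -1.81 to 0.281 with a sample left out, where the call was gained without high OC replicate 1 (-1.81, adjusted p = 0.0248). CHG promoters gave 2.90 with 1 per 1 kb. At 20 reads CHG promoters gave 13.8 and CHH promoters -3.54; with a sample left out, CHG promoters gave 2.53 to 4.07 and CHH promoters -0.831 to 0.348. Overlap by position gave 32.7% for CHG and 34.0% for CHH. The share of runs that were higher was 60% at 20 reads, with 15 runs left, and runs at promoters differed by 11.1 points at 20 reads and 0.476 to 11.1 with a sample left out. Apart from counts that shrank by construction, the cause was not tested. A promoter of 1 kb, lists not matched and a test of list size were not run, since promoter limits and the full set of tested sites were not used here; sites inside a gene or promoter are those of the main count. At the depth of the unselected CpG sites and the overdispersion set at 0.02, 71.8% of simulated changes of 30 points were recovered, so smaller differences at single sites can be missed. Where samples of a group vary more than that setting, larger differences can be missed too.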

Other observations

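The test of the sample order, the test on sites under 50 reads and the count of sites by the authors' criteria under other splits were chosen after related results were seen, and so were the patterns below. Further promoters with several listed CpG sites were also singled out after their values were seen, and their levels again cover the listed sites only. NFKBIB, an inhibitor of NF-kappa-B, and SIRT2, a NAD-dependent deacetylase, share a promoter stretch with 6 sites, all higher, at 40.3% ± 5.30 (SD, n = 3) against 14.5% ± 7.79 (SD, n = 3). PRDX2, a peroxiredoxin, and RNASEH2A share another with 6 sites, all higher, at 76.7% ± 4.63 (SD, n = 3) against 54.7% ± 5.49 (SD, n = 3). LOXL1, an elastic fibre crosslinking enzyme, had 6 higher sites at 61.7% ± 5.15 (SD, n = 3) against 37.2% ± 5.19 (SD, n = 3), and NID2, a basement membrane nidogen, had 6 at 36.0% ± 4.14 (SD, n = 3) against 15.8% ± 3.24 (SD, n = 3). Of the tight junction gene CLDN5 4 promoter sites were higher and 0 lower, and of FZD1 5 and 0. Promoters that leaned lower included PRDM7, with 5 of 6 sites lower and a mean of 48.4% ± 6.19 (SD, n = 3) against 74.7% ± 7.76 (SD, n = 3), ACOT7, with 5 of 6 lower at 18.5% ± 1.74 (SD, n = 3) against 36.4% ± 7.57 (SD, n = 3), and TBX1, with 5 lower and 0 higher.

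Sites higher in high OC skin lay in promoters more often than lower sites, by 4.97 points. Dense clusters within 1 kb do not account for all of it, since 1 site per 1 kb window left 4.0 points (odds ratio 1.73, against 1.96 over all sites). Clusters wider than 1 kb still counted more than once there, so their part was not tested. Shallow coverage, as counted, does not account for it either, since 10.7 points remained with at least 20 reads in each sample. Reads counted doubly would let shallower sites pass that minimum. Low OC replicate 3 was the highest of its group at 34.5% of the higher promoter sites. This decides nothing about a gradient in which it stands nearest to the high OC samples, as it does at the OTX1 promoter, since the sites were selected for a small spread within the groups. At the 292 unselected CpG sites, low OC replicate 3 differed from high OC replicates 1, 2 and 3 at 21, 11 and 19 sites (Fisher's exact test, unadjusted p under 0.05). It differed from low OC replicates 1 and 2 at 33 and 24 sites. On that stretch it stood nearer to the high OC samples, which goes with such a gradient. The stretch does not speak for the listed promoters. What stays open is such a gradient, a chance division of the 6 samples, whatever the BPT and BPL titles mark, and contaminant load itself. A difference between the animals in age, sex, body condition or the makeup of the skin, which the labels do not give, stays open as well. The lists were selected on the labelled groups and cannot be split another way.

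At 46 listed CpG sites the groups differed by 75 points or more, among them the HSPG2 and PAXIP1 sites. Sequence variants that make or break a CpG in some animals are a candidate explanation, because such a variant changes a single site while methylation tends to change over a stretch. Another listed site of the same direction within 100 bases, the site's own partner on the opposite strand left aside, was found at 23.9% of them (exact 95% interval 12.6% to 38.8%). The share was 31.4% among sites under 50 points and 48.6% among sites between 50 and 75 points. The difference from sites under 50 points was not significant (Fisher's exact p = 0.341), so with 46 sites the 2 readings cannot be told apart. Levels within 10 points of 0, 50 or 100% in all 6 samples, as a variant would give, stood at 9 of the 46 sites (19.6%), 4.49% of sites between 50 and 75 points and 0.169% of sites under 50 points. A difference of 75 points by itself pushes levels towards 0 and 100%, so this rise decides nothing either. A neighbour of the opposite direction, as in HSPG2, stood beside 17.4% of the 46 sites and 4.75% of sites under 50 points (Fisher's exact p = 0.00135), a contrast computed after the HSPG2 sites were seen.

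Listed CHG and CHH sites within 100 bases had the same direction in 137 of 138 and 718 of 720 pairs. Molecules that bisulfite left unconverted may produce this, since every cytosine of such a read counts as methylated, and the identical read counts of 52.5% of near CHH pairs go with it. In the unselected sites, a non-CpG cytosine with a methylated read had a methylated neighbour in its own sample 1.25 times as often as in the other samples, short of the 1.5 times set before the test, but the neighbours were so often methylated anywhere that 1.43 was the highest ratio within reach. At sites under 50 reads the ratio was 1.34, with 1.59 within reach, so this test was able to reach 1.5 and fell short. Its bound was set after related results were seen and lay near the highest ratio within reach, and a ratio above 1 goes with unconverted molecules as well, so the explanation cannot be told apart from methylation of whole stretches outside CpG.

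The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real groups gave 3 called CpG sites and the highest of the other splits 13; 4 of the 10 splits, the real groups included, gave 3 or more. That split set high OC replicate 1 with low OC replicates 1 and 2 against high OC replicates 2 and 3 with low OC replicate 3. For CHG sites all 10 splits gave 0 calls, and for CHH sites all 10 gave at least the 1 call of the real groups, with 2 as the highest. By the criteria of the authors' lists recomputed on the 651 CpG sites, the real groups gave 14 sites, where the authors called 13, and the highest other split 27, and 6 of the 10 splits, the real groups included, gave 14 or more. In the real groups 8 of these sites were higher and 6 lower. Other splits ran from an even count (7 and 7) to uneven ones (19 and 6, 6 and 21, 2 and 10). On this stretch a lean to 1 direction thus also arose under other splits.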
